A study of Mus musculus with 24 samples.

How the data were processed

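RNA from 24 liver samples of male mice was sequenced, in 4 groups of 6 libraries given by the labels: elemental control, elemental MR, casein control and casein MR. The labels give total RNA as the molecule. The selection of RNA, the strand of the libraries, the aligner, the counting tool and the genome build are not given in the sources used here, so no positions are given.

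The deposited raw table holds read counts, as whole numbers per Ensembl gene and library, for 15161 genes. Each gene in it has a total of at least 72 reads over the 24 libraries, and the rule behind this limit is not stated. The deposited normalized table holds a signal, which was checked to equal the raw counts divided by 1 size factor per library. These factors ran from 0.745 to 1.32 and matched median-of-ratios factors recomputed from the raw table. Only the raw counts entered the tests. Symbols came from the deposited table for 13002 genes and from the reference annotation for 2119 more, and 40 genes had none.

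Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed by filterByExpr with the groups, which left 13441 genes and 99.93% of the reads. Libraries were scaled by the trimmed mean of M values (TMM), and all 24 libraries entered 1 quasi-likelihood fit with a mean per group. The common biological coefficient of variation was 0.159. The p-values were adjusted by Benjamini and Hochberg's method within each comparison, and genes with an adjusted p under 0.05 were called. Standard errors were derived from the log2 fold change and its F statistic. CPM are counts scaled to the TMM-scaled library size, and a prior count of 2 was added for log2 CPM.

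The comparisons were MR against control with elemental amino acids, MR against control with casein, the difference between these effects (casein minus elemental), and casein against elemental on the control diets and on the MR diets. The MR comparisons have no library in common. The libraries carry no shared numbers, so no pairing was possible, and the labels name no batch. Before the data were examined, the tests, the 5 comparisons, 32 gene lists from general knowledge of liver, the rule for named genes and the alternatives were written down, except for those named as added later. The rule took the 10 largest rises and 10 largest falls of each MR comparison, and 8 in each direction for the other comparisons. It took them among called genes with an average log2 CPM of at least 1 and a symbol that is not a predicted or clone name. It also took 22 genes fixed in advance and, for each list described, the 4 members with the smallest p.

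Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes and again with a correlation estimated for each list, and p-values were adjusted over the lists within a comparison. Members past the threshold were counted over all genes tested and adjusted over the list alone. Measures of the libraries were compared by two-sided exact permutation tests, adjusted over 28 tests. The 60 pairs of libraries within groups held 0 identical pairs.

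The code was tested on simulated counts with the library sizes and spread per gene of the whole fit, which were the same for each comparison. In each, 67 genes were changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold, so the ranges below include sampling noise. No genes of low average count were changed. With edgeR, 49.3% (casein MR, 13273 genes) to 68.7% (MR diets, 13287 genes) of the genes made to change 1.5-fold were called, and 73.1% (difference, 13295 genes) to 92.5% (casein MR) of those changed 2-fold. Of the genes called in a comparison, 3 of 163 (casein MR) to 10 of 174 (elemental MR, 13276 genes) had not been changed.

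Alternatives were DESeq2 size factors, upper quartile scaling, no filter on low counts, a stricter filter of at least 1 CPM in every library of a group, 1 surrogate variable (sva 3.50.0), the DESeq2 Wald test (1.42.0), limma-voom with sample quality weights, a fit of the compared groups alone, an adjusted p under 0.01, a change of at least 2-fold, and leaving out each library in turn. A robust prior for the spread, and the counts of list members without C_MR_3438, were added after the data were seen, and so were 95% t intervals of the differences between the MR effects in mean log2 CPM of lists. Labels were also exchanged among the libraries compared in 50 splits, the real one included, drawn with a fixed seed. The results of some named genes are not reported here. No sample was left out of the main tests, and 0 per-sample columns were left unused.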

Results

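RNA levels were measured by sequencing in liver samples of male C57BL6/J mice, an inbred laboratory strain, at 4 months of age. The series compared methionine restriction (MR) in purified diets whose protein came either from free amino acids, called elemental here, or from casein, the main milk protein, which was oxidised for MR. Oxidation turns methionine into forms the body uses poorly, so it lowers the usable methionine of an intact protein. Control diets held 0.86% methionine and MR diets 0.17%. The 24 libraries formed 4 groups of 6, namely elemental control, elemental MR, casein control and casein MR, and each library carried its own 4-digit number.

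Library totals ran from 13.5 to 20.8 M counted reads, and the group means were 17.2 ± 2.36 M for elemental control, 16.5 ± 1.17 for elemental MR, 16.0 ± 1.68 for casein control and 17.4 ± 1.85 for casein MR (SD, n = 6 each). Depth did not separate the groups in any of 4 contrasts (lowest exact permutation p = 0.19, adjusted p = 0.332). After the filter on low counts 13441 genes were tested. Single libraries are named as in their labels (E and C for elemental amino acids and casein, then control or MR and a number). The numbers were not stated to be mice, so the p-values measure the spread between these samples.

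The make-up of the libraries moved with diet. The 20 most abundant genes took 37.6 ± 0.87% of reads in elemental control and 32.9 ± 0.544% in elemental MR. They took 36.8 ± 0.62% in casein control and 30.7 ± 0.512% in casein MR (SD, n = 6; exact permutation p = 0.00216 for each MR contrast, the smallest p that 6 against 6 libraries allow). Albumin transcripts (Alb) took 7.42 ± 0.167, 6.43 ± 0.222, 6.69 ± 0.594 and 4.90 ± 0.182% in the same order, and the share was also lower in casein control than in elemental control (exact permutation p = 0.0108). Mitochondrially encoded transcripts went from 14.8 ± 0.979% to 12.3 ± 0.404% with elemental MR and from 14.3 ± 0.814% to 12.2 ± 0.621% with casein MR (exact permutation p = 0.00216 for each). The first principal component held 29.1% of the variance of log2 CPM (counts scaled to library size) and placed the MR libraries at 9.22 or higher and the control libraries at -16.8 or lower. The second component held 8.01% and placed the casein libraries at -6.13 or lower and the elemental libraries at -0.207 or higher.

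**Figure D1:**
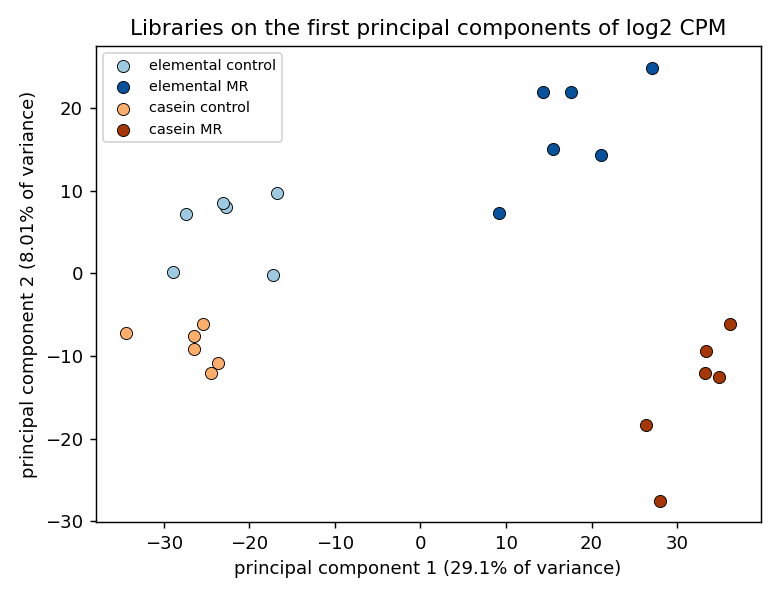
Scores of the 24 libraries on principal component 1 (x axis, 29.1% of variance) and principal component 2 (y axis, 8.01%) of log2 CPM, with 1 point per library coloured by group. The 12 MR libraries lie right of the 12 control libraries, and the casein libraries lie below the elemental ones on the y axis.

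The elemental MR diet was compared with its control to measure the effect of MR with free amino acids. Targets of ATF4 and genes of the NRF2 and glutathione list rose, and a set of genes with higher expression in male than female mouse liver fell. Asns (ENSMUSG00000029752), which makes asparagine, went from 7.57 ± 2.55 to 70.6 ± 8.38 CPM (SD, n = 6), a log2 fold change of 3.23 ± 0.20 (SE; adjusted p = 3.26e-11). Largest, here and below, is meant among called genes with an average log2 CPM of at least 1 and a symbol that is not a predicted or clone name, and called genes below that level, such as Cyp2b13, could have larger values. The largest rise was that of Cyp2b9 (ENSMUSG00000040660), a female-biased cytochrome P450, from 1.99 ± 1.19 to 69.6 ± 47.1 CPM (log2 fold change 5.12 ± 0.51, adjusted p = 7.78e-08). In all, 1803 genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 911 higher and 892 lower with MR, and 327 of them changed at least 2-fold (119 higher, 208 lower). The larger direction turned with upper quartile scaling (807 higher, 945 lower) and at an adjusted p under 0.01 (473 higher, 501 lower).

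Below Cyp2b9, the largest rises with elemental MR were those of the P450 genes Cyp2a4 (4.96 ± 0.68) and Cyp2a22 (4.07 ± 0.50), the serine synthesis gene Psat1 (3.98 ± 0.25), the glutathione S-transferase Gsta1 (3.78 ± 0.42) and the transporter Slc22a26 (3.66 ± 0.61; log2 fold change ± SE). Aldh1l2, a mitochondrial folate enzyme, rose by 3.48 ± 0.37, Cox6a2, a subunit of cytochrome c oxidase known from muscle, by 3.27 ± 1.03, and the transporter Slc22a27 by 3.25 ± 0.46. The call of Cox6a2 (adjusted p = 0.0335) was lost under limma-voom with quality weights (adjusted p = 0.143), and in 7 of the 24 fits that left out 1 library (highest adjusted p = 0.0666). The largest falls were those of the trefoil peptide Tff3 (-3.88 ± 0.69), Cyp4a12b (-3.87 ± 0.47), Selenbp2 (-3.77 ± 0.47), Cib3 (-3.71 ± 0.65) and Dct (-3.67 ± 0.39). The clock-associated repressor Bhlhe41 (-3.48 ± 0.62), the secreted serpins Serpina12 (-3.39 ± 0.27) and Serpina1e (-3.28 ± 0.59), the pseudogene Serpina4-ps1 (-3.20 ± 0.90) and the acetylcholine receptor subunit Chrna4 (-3.20 ± 0.62) followed. The value of Serpina4-ps1 was -7.49 (adjusted p = 3.47e-04) without E_MR_3420. Cyp2a, Cyp2b, Cyp4a, Gsta, Slc22a, Mup, Acot and Serpina1 genes have near-identical copies, and reads may have been split between copies, so single values in these families are uncertain.

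Of 32 tested targets of ATF4, the transcription factor of the amino acid and integrated stress response, 20 rose and 0 fell with elemental MR (24 and 0 adjusted over the list alone; camera adjusted p = 4.05e-32, and adjusted p = 2.68e-05 with an estimated correlation). Besides Asns and Psat1, the members with the smallest p were the lipoprotein receptor Vldlr (2.50 ± 0.17) and the amino acid transporter subunit Slc3a2 (1.14 ± 0.12). Phgdh, the first enzyme of serine synthesis, rose by 4.38 ± 0.51 (adjusted p = 1.16e-06). Ddit4 (0.04 ± 0.26, adjusted p = 0.952), the secreted factor Gdf15 (0.40 ± 0.30, adjusted p = 0.449) and the hormone Fgf21 (1.69 ± 0.62, adjusted p = 0.0691) did not pass the test. Fgf21 stood at 4.56 ± 4.87 CPM in elemental control and 14.7 ± 13.1 CPM in elemental MR (SD, n = 6). Of 20 cytosolic aminoacyl-tRNA synthetases, 7 rose and 0 fell (10 and 0 adjusted over the list alone), led by Gars (0.94 ± 0.07); the list had an adjusted p = 4.62e-05, but adjusted p = 0.171 with an estimated correlation.

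Of 35 tested NRF2 targets and genes of glutathione metabolism, 24 rose and 1 fell (24 and 1 adjusted over the list alone; adjusted p = 4.59e-37, and adjusted p = 4.71e-04 with an estimated correlation). Examples were the glutathione S-transferases Gsta2 (3.18), Gsta4 (1.59) and Gstm1 (1.46) and the epoxide hydrolase Ephx1 (1.47 on the log2 scale). Gstm3 rose by 1.62 ± 0.22 and Gclc, the rate-limiting enzyme of glutathione synthesis, by 0.72 ± 0.11.

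Of 23 male-biased liver genes, 22 fell and 0 rose with elemental MR (the same counts adjusted over the list alone; median log2 fold change -1.66, adjusted p = 6.06e-33, and adjusted p = 0.0188 with an estimated correlation). Cyp4a12b, Selenbp2, the complement component C6 (-2.58) and Susd4 (-2.60) had the smallest p. Of 17 female-biased genes, 10 rose and 0 fell (12 and 1 adjusted over the list alone; adjusted p = 1.65e-11, and adjusted p = 0.0188 with an estimated correlation), among them the flavin monooxygenase Fmo1 (0.74).

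Of 26 genes of fatty acid and triglyceride synthesis, 13 fell and 0 rose with elemental MR (15 and 2 adjusted over the list alone; adjusted p = 9.53e-09, but adjusted p = 0.133 with an estimated correlation). Scd1, which desaturates stearate, went from 4159 ± 1570 to 1048 ± 383 CPM (-1.99 ± 0.31, adjusted p = 6.04e-05), and Thrsp (-2.34), Pklr (-1.06), Fasn (-0.99 ± 0.29) and Srebf1 (-0.80 ± 0.17) also fell. Of 25 genes of cholesterol synthesis and uptake, 3 fell and 0 rose (4 and 0 adjusted over the list alone; adjusted p = 0.0102, but adjusted p = 0.791 with an estimated correlation). Of 39 PPARalpha targets and genes of fatty acid oxidation, 14 rose and 3 fell (21 and 4 adjusted over the list alone; adjusted p = 4.77e-07, but adjusted p = 0.281 with an estimated correlation). Cyp4a14 (2.04 ± 0.34), the fatty acid transporter Cd36 (1.74) and the thioesterase Acot2 (1.29) rose, and Cpt1a, which admits fatty acids to mitochondria, had a log2 fold change of -0.13 ± 0.11 (adjusted p = 0.51).

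Of 22 genes of the unfolded protein response of the endoplasmic reticulum, 16 fell and 0 rose with elemental MR (17 and 1 adjusted over the list alone; adjusted p = 7.39e-13, but adjusted p = 0.0772 with an estimated correlation). Creld2 (-1.28), Sdf2l1 (-1.19), Manf (-1.09) and the disulfide isomerase Pdia6 (-0.70) led. Of 29 interferon-stimulated genes, 9 rose and 0 fell (12 and 0 adjusted over the list alone; adjusted p = 1.08e-06, but adjusted p = 0.17 with an estimated correlation). Usp18 (1.29) led the list. Of 19 clock genes, 8 fell and 0 rose (10 and 0 adjusted over the list alone; adjusted p = 0.00212, but adjusted p = 0.122 with an estimated correlation), among them Per2 (-1.33) and Nr1d1 (-0.57). In the methionine cycle list of 26 genes, 7 rose and 3 fell (7 and 5 adjusted over the list alone), with an adjusted p of 0.685. Mat1a, which makes S-adenosylmethionine, rose by 0.55 ± 0.11, and Cth, the last enzyme of cysteine synthesis, rose by 0.77 ± 0.20, while Cbs had a value of 0.15 ± 0.10 (adjusted p = 0.378). Igf1 fell by 0.34 (SE 0.08, adjusted p = 0.0067). Of 26 acute phase genes, 10 fell and 3 rose (12 and 5 adjusted over the list alone; adjusted p = 0.0526). Of 20 pericentral hepatocyte markers, 7 fell and 0 rose (the same adjusted over the list alone; adjusted p = 0.00157, but adjusted p = 0.17 with an estimated correlation). Igfbp1 (0.84 ± 0.31, adjusted p = 0.0699), Pck1 (0.09 ± 0.28, adjusted p = 0.89) and Cyp7a1 (0.04 ± 0.39, adjusted p = 0.972) did not pass.

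Markers of other cell types were tested as well. Of 20 Kupffer cell and macrophage markers 1 rose (1 adjusted over the list alone; adjusted p = 0.83) and of 20 endothelial markers 1 rose (0 adjusted over the list alone; adjusted p = 0.685). Of 14 lymphocyte and neutrophil markers 1 fell (1 adjusted over the list alone; adjusted p = 0.574). Of 19 stellate cell and fibroblast markers 2 fell (2 adjusted over the list alone; adjusted p = 0.00509, but adjusted p = 0.17 with an estimated correlation). Of 9 cholangiocyte markers 1 fell (1 adjusted over the list alone; adjusted p = 0.00793, but adjusted p = 0.133 with an estimated correlation). Of 9 erythroid markers 3 fell and 1 rose (3 and 1 adjusted over the list alone; adjusted p = 0.00896, but adjusted p = 0.416 with an estimated correlation).

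The casein MR diet was compared with the casein control to measure the effect of MR with oxidised casein as protein source. The casein control diet was not labelled as oxidised. MR and oxidation therefore cannot be told apart here or in the difference between the MR effects. ATF4 targets and genes of the NRF2 and glutathione list rose here too, male-biased genes fell, and genes of fatty acid oxidation rose. Asns went from 1.97 ± 1.09 to 62.3 ± 7.27 CPM (log2 fold change 5.01 ± 0.24, adjusted p = 6.81e-14) and Psat1 from 0.952 ± 0.565 to 35.7 ± 3.69 CPM (5.19 ± 0.28, adjusted p = 3.46e-13; SD, n = 6). Bhmt, which remethylates homocysteine with betaine, went from 892 ± 196 to 93.2 ± 22.3 CPM and fell by 3.26 on the log2 scale. In all, 3137 genes passed the test, 1427 higher and 1710 lower with MR, and 674 changed at least 2-fold (300 higher, 374 lower). The number of genes called was 2052 with 1 surrogate variable in the model.

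The largest rises with casein MR were those of Cyp2a4 (6.05 ± 0.68) and Cyp2b9 (5.82 ± 0.50), followed by Psat1, Asns and the transcription factor gene Tcf24 (4.77 ± 0.34). The rule for named genes also took the skeletal muscle genes Ttn (5.33 ± 1.26), Acta1 (4.97 ± 1.18), Myl1 (4.95 ± 1.20), Tnnc2 (4.71 ± 1.17) and Tnnt3 (4.61 ± 1.10). Their rise rested on 1 library. Acta1, skeletal muscle actin, was at 644 CPM in C_MR_3438 and at 19.8 CPM or less in the other 23 libraries, and without C_MR_3438 its log2 fold change was 0.51 (adjusted p = 0.588). Without that library 2894 genes were called with casein MR, 1287 higher and 1607 lower. The largest falls were those of Dct (-6.55 ± 0.49), the steroid dehydrogenase Hsd3b5 (-6.52 ± 0.70), Selenbp2 (-6.08 ± 0.53), Tff3 (-5.61 ± 0.73) and Serpina12 (-5.15 ± 0.29). Chrna4 (-4.11 ± 0.65), the major urinary protein gene Mup12 (-3.97 ± 0.48), the adhesion molecule Ncam2 (-3.91 ± 0.29), the organic anion transporter Slc22a7 (-3.87 ± 0.28) and Cib3 (-3.84 ± 0.66) followed.

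Of the 32 ATF4 targets, 20 rose and 0 fell with casein MR (21 and 1 adjusted over the list alone; adjusted p = 6.27e-22, and adjusted p = 2.29e-04 with an estimated correlation). Asns, Vldlr (3.88), Psat1 and Aldh1l2 (4.55) led the list. Phgdh rose by 4.39 ± 0.54 (adjusted p = 5.41e-07), while Fgf21 (1.62 ± 0.69, adjusted p = 0.0954), Gdf15 (0.55 ± 0.30, adjusted p = 0.212) and Ddit4 (-0.08 ± 0.25, adjusted p = 0.871) did not pass. Of 20 aminoacyl-tRNA synthetases, 9 rose and 0 fell (11 and 2 adjusted over the list alone; adjusted p = 4.22e-04, but adjusted p = 0.209 with an estimated correlation). Of 35 NRF2 and glutathione genes, 22 rose and 3 fell (23 and 3 adjusted over the list alone; adjusted p = 2.81e-27, and adjusted p = 0.00229 with an estimated correlation). Gstm1 (1.80), Gstm4 (1.84), Gsta2 (3.45) and Ephx1 (1.77) led the list. Gstm3 rose by 1.73 ± 0.22 and Gclc by 0.82 ± 0.11.

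Of the 23 male-biased genes, 21 fell and 0 rose with casein MR (the same counts adjusted over the list alone; median -2.26, adjusted p = 1.18e-25, and adjusted p = 0.021 with an estimated correlation). Of the 17 female-biased genes, 12 rose and 2 fell (the same adjusted over the list alone; median 2.59, adjusted p = 3.2e-08, and adjusted p = 0.021 with an estimated correlation).

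Of 39 PPARalpha targets and genes of fatty acid oxidation, 30 rose and 1 fell with casein MR (the same counts adjusted over the list alone; adjusted p = 2.54e-27, and adjusted p = 0.0199 with an estimated correlation). Cyp4a14 (4.22 ± 0.38), Cyp4a31 (4.10), Acot2 (2.97) and the acyl-CoA dehydrogenase Acadl (0.62) led, and Cpt1a had a value of -0.19 ± 0.11 (adjusted p = 0.244). Of 26 genes of fatty acid and triglyceride synthesis, 18 fell and 2 rose (19 and 3 adjusted over the list alone; adjusted p = 2.74e-07, but adjusted p = 0.127 with an estimated correlation). Pklr (-1.57), Thrsp (-3.48), Agpat2 (-0.69) and Dgat2 (-0.61) led the list. Scd1 fell by 1.99 (SE 0.31), Fasn by 1.62 (SE 0.29) and Srebf1 by 0.77 (SE 0.17). Of 25 genes of cholesterol synthesis and uptake, 18 fell and 0 rose (22 and 0 adjusted over the list alone; adjusted p = 1.27e-07, but adjusted p = 0.302 with an estimated correlation). Ebp (-0.53), Sc5d (-0.83), Dhcr7 (-1.20) and Tm7sf2 (-0.92) led the list.

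Of 34 genes of the urea cycle and amino acid catabolism, 22 fell and 0 rose with casein MR (24 and 1 adjusted over the list alone; adjusted p = 1.35e-10, but adjusted p = 0.117 with an estimated correlation). Oat (-1.45), Prodh (-1.13), Shmt1 (-0.59) and Otc (-0.54) led the list. Of 26 acute phase genes, 19 fell and 3 rose (the same adjusted over the list alone; adjusted p = 5.25e-08, and adjusted p = 0.021 with an estimated correlation), among them Orm1 (-3.35) and the fibrinogen chain Fga (-0.61). In the methionine cycle list of 26 genes, 10 fell and 5 rose (13 and 9 adjusted over the list alone; adjusted p = 0.0192, but adjusted p = 0.125 with an estimated correlation). Bhmt, the methyltransferases Nnmt (-3.03 ± 0.32), Gnmt (-1.0) and Gamt (-0.998) fell, and Mat1a (0.25 ± 0.11, adjusted p = 0.119), Cth (0.32 ± 0.20, adjusted p = 0.285) and Cbs (0.14 ± 0.10, adjusted p = 0.357) did not pass. Of 20 periportal hepatocyte markers, 13 fell and 2 rose (14 and 3 adjusted over the list alone; adjusted p = 2.89e-09, and adjusted p = 0.0199 with an estimated correlation). Pigr (-1.80), Alb (-0.71), Cyp2f2 (-1.40) and Igf1 (-0.84) led the list. Of 20 pericentral markers, 12 fell and 0 rose (the same adjusted over the list alone; adjusted p = 8.37e-09, and adjusted p = 0.0199 with an estimated correlation), among them Gulo (-1.43), Lect2 (-1.23) and the glutamine synthetase gene Glul (-0.65).

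Of 19 genes of bile acid synthesis and transport, 9 fell and 0 rose with casein MR (the same adjusted over the list alone; adjusted p = 2.73e-04, and adjusted p = 0.021 with an estimated correlation), among them the bile acid importer Slc10a1 (-0.77). Cyp7a1, the rate-limiting enzyme, had a value of -0.32 ± 0.39 (adjusted p = 0.62). Of 22 unfolded protein response genes, 14 fell and 0 rose (16 and 0 adjusted over the list alone; adjusted p = 2.49e-06, but adjusted p = 0.165 with an estimated correlation). Of 29 interferon-stimulated genes, 16 rose and 1 fell (21 and 1 adjusted over the list alone; adjusted p = 8.79e-07, but adjusted p = 0.125 with an estimated correlation). Zbp1 (1.10), Usp18 (1.06), Ifi44 (1.23) and Igtp (1.28) led the list. Of 19 clock genes, 10 fell and 0 rose (11 and 1 adjusted over the list alone; adjusted p = 0.014, but adjusted p = 0.15 with an estimated correlation). Of 21 immediate early and heat shock genes, 8 rose and 0 fell (the same adjusted over the list alone; adjusted p = 8.71e-04, but adjusted p = 0.125 with an estimated correlation). The chaperones Hspb1 (2.01), Hspe1 (0.44) and Hspd1 (0.45) led the list. Pck1 (0.00 ± 0.28, adjusted p = 0.999) and Igfbp1 (0.81 ± 0.31, adjusted p = 0.0573) did not pass. Among other cell types, 1 of 20 Kupffer cell and macrophage markers rose (1 adjusted over the list alone). This list had an adjusted p = 0.0504, adjusted p = 0.0276 without C_MR_3438, and adjusted p = 0.626 with an estimated correlation. Its mean log2 CPM was 5.1 in C_MR_3431 and 4.41 to 4.5 in the other casein MR libraries. Of 20 endothelial markers 1 fell (1 adjusted over the list alone, adjusted p = 0.748). Of the biliary cells, 4 of 9 cholangiocyte markers fell (4 adjusted over the list alone; adjusted p = 0.0112, but adjusted p = 0.125 with an estimated correlation).

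**Figure D2:**
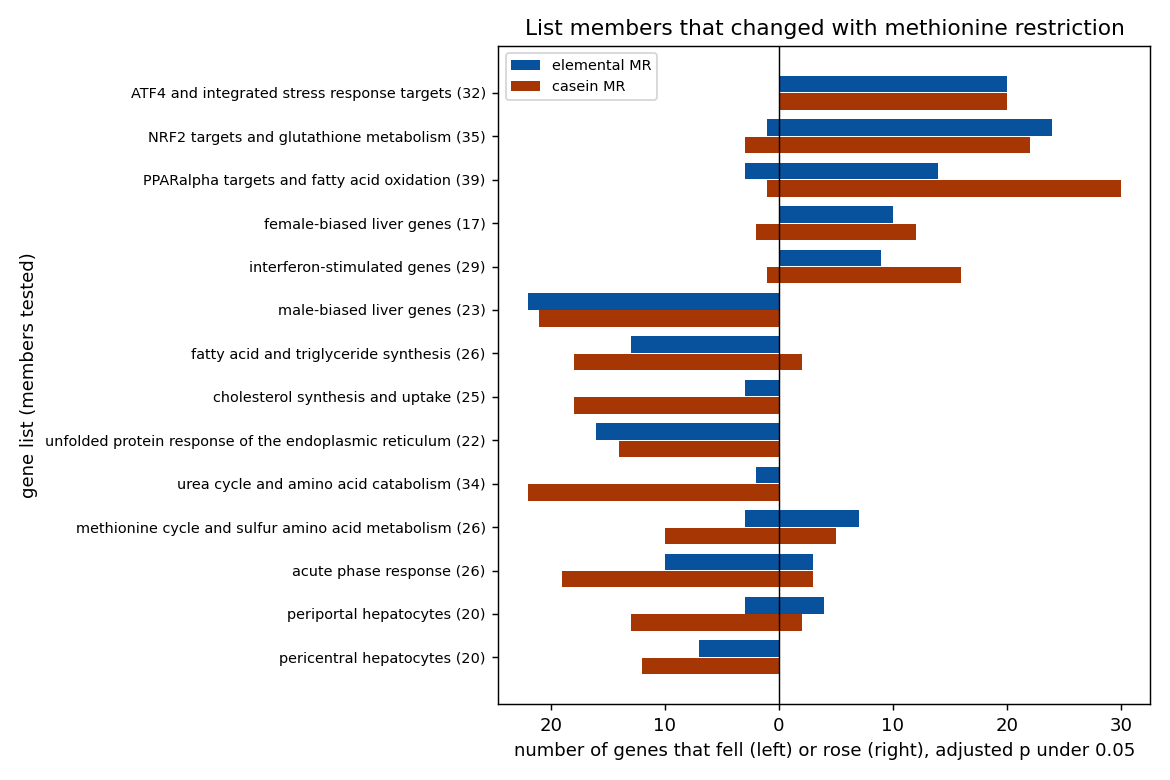
Number of members that rose (right of 0) or fell (left of 0) at an adjusted p under 0.05 in 14 of the gene lists fixed in advance, with elemental MR and with casein MR (x axis, number of genes; y axis, list with the number of members tested). The ATF4 list has 20 rises in both comparisons, and the list of PPARalpha targets and fatty acid oxidation has 14 rises with elemental MR and 30 with casein MR.

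The MR effects were then compared with each other, since they share no libraries. Of 13441 genes, 579 were higher and 681 lower with MR in both comparisons, against 96.7 and 114 for independent lists of these sizes, and 11 were called in opposite directions, against 211. The log2 fold changes of all tested genes correlated across genes with Pearson's r of 0.685 and Spearman's rho of 0.536, and genes are not independent replicates. Of the 1803 genes called with elemental MR, 1704 (94.5%) had the same sign with casein MR. Of the 1260 genes shared in the same direction, 841 had the larger absolute change with casein and 419 with elemental amino acids. The median ratio of the absolute change with casein to that with elemental amino acids was 0.955 over the genes called with elemental MR and 1.82 over those called with casein MR, so it depended on how genes were selected.

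**Figure D3:**
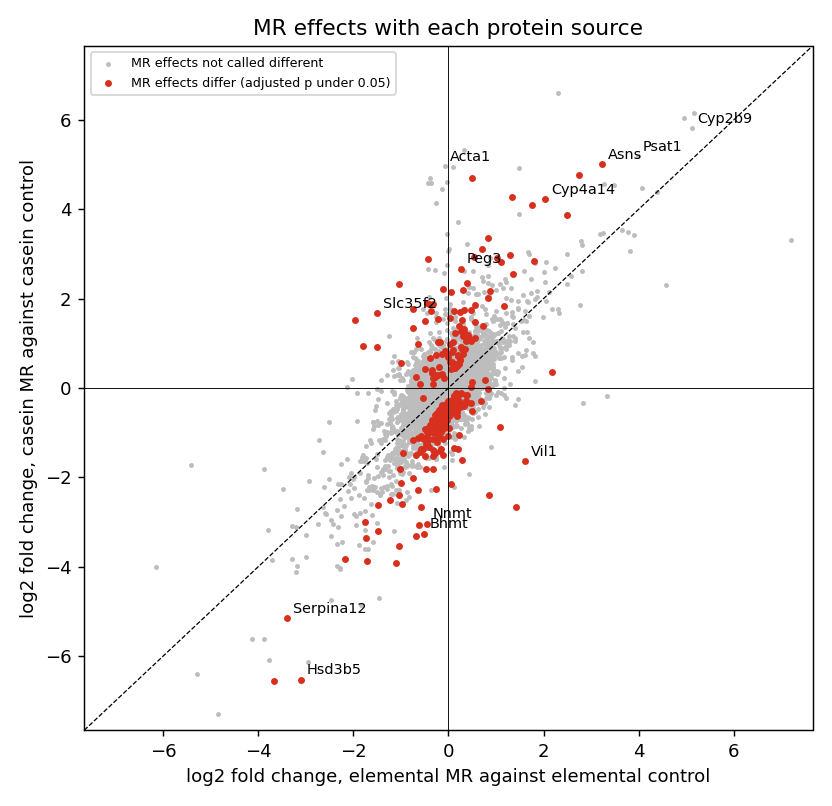
Log2 fold change with elemental MR (x axis) against log2 fold change with casein MR (y axis) for 13441 tested genes, with genes whose MR effects differed at an adjusted p under 0.05 in colour (315 genes) and the line of equal change dashed. Labelled genes are named in the text, and Pearson's r across genes was 0.685.

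The test of the difference between the MR effects asked whether oxidised casein gave another response than elemental amino acids. The methionine cycle and periportal lists had lower values in the casein MR effect than in the elemental MR effect, where neither list was called, and the PPARalpha and fatty acid oxidation list had higher ones. Bhmt stood at 840 ± 214 and 587 ± 167 CPM in elemental control and elemental MR (log2 fold change -0.52 ± 0.19, adjusted p = 0.0647). It stood at 892 ± 196 and 93.2 ± 22.3 CPM in casein control and casein MR (SD, n = 6). This gave a difference of -2.74 ± 0.27 between the log2 fold changes (SE, adjusted p = 1.73e-06). Peg3, an imprinted gene, was at 4.49 ± 0.971, 5.34 ± 1.52, 3.51 ± 1.04 and 22.7 ± 2.80 CPM in elemental control, elemental MR, casein control and casein MR (difference 2.41 ± 0.26, adjusted p = 3.43e-06). In all, 315 genes had different MR effects, 105 with the higher and 210 with the lower value with casein, and 97 differed at least 2-fold (51 higher, 46 lower). Of the 315, 293 were called with casein MR, 128 with elemental MR and 2 with neither. With 1 surrogate variable in the model 193 genes were called.

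The largest positive differences were those of Slc35f2 (3.15 ± 0.61), the acyltransferase Mogat1 (2.53 ± 0.59), the keratin Krt23 (2.53 ± 0.41), Peg3, Sema5b (2.41 ± 0.37), the peroxisomal oxidation enzyme Ehhadh (2.40 ± 0.50), Cyp4a31 (2.35 ± 0.39) and Adgrg2 (2.33 ± 0.33). The largest negative differences were those of Hsd3b5 (-3.42 ± 0.84), the prostaglandin D synthase Ptgds (-3.27 ± 0.58), the actin-bundling villin gene Vil1 (-3.25 ± 0.87) and Dct (-2.88 ± 0.74). Ncam2 (-2.80 ± 0.38), Bhmt, Nnmt (-2.58 ± 0.43) and the apolipoprotein gene Apoa4 (-2.51 ± 0.59) followed. With 1 surrogate variable the adjusted p was 0.0955 for Hsd3b5, 0.125 for Vil1 and 0.139 for Dct. The call of Hsd3b5 was lost in 2 of the 24 fits that left out 1 library, among them that without E_MR_3420 (-2.20, adjusted p = 0.0693). That of Vil1 was lost in 14 of these fits (highest adjusted p = 0.19) and that of Dct in 8 (highest adjusted p = 0.0753). Igf1 (-0.50 ± 0.12, adjusted p = 0.0191) and Cyp4a14 (2.17 ± 0.47, adjusted p = 0.00906) also differed. The difference for Asns was 1.78 ± 0.31 and that for Tcf24 2.02 ± 0.46. Elemental MR and casein MR themselves differed by -0.18 ± 0.18 for Asns (adjusted p = 0.653) and by -0.57 ± 0.23 for Tcf24 (adjusted p = 0.15), and both genes were lower in casein control than in elemental control.

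Of 39 PPARalpha targets and genes of fatty acid oxidation, 15 rose more and 0 less with casein (25 and 0 adjusted over the list alone; median difference 0.39, adjusted p = 2.28e-25, and adjusted p = 0.0256 with an estimated correlation). Besides Cyp4a31, the examples were Acot2 (1.68), Acot1 (1.73) and Acadl (0.38). Of 20 periportal markers, 9 were lower and 0 higher (13 and 0 adjusted over the list alone; median -0.54, adjusted p = 4.59e-21, and adjusted p = 0.00117 with an estimated correlation). Pigr (-1.32), Cyp2f2 (-1.22), Aldh1b1 (-1.47) and Cdh1 (-0.65) led the list. Of 26 methionine cycle genes, 4 were lower and 0 higher (7 and 2 adjusted over the list alone; adjusted p = 5.16e-05, and adjusted p = 0.0154 with an estimated correlation), namely Bhmt, Nnmt, Gnmt (-0.75) and Gamt (-0.56). Of 26 acute phase genes, 4 were lower and 0 higher (10 and 0 adjusted over the list alone; adjusted p = 1.29e-08, and adjusted p = 0.0161 with an estimated correlation), among them Orm1 (-1.62) and Fga (-0.36). On the control diets the acute phase list was higher with casein (mean 0.29, 0 members called and 0 adjusted over the list alone; adjusted p = 2.99e-04, but adjusted p = 0.32 with an estimated correlation). On the MR diets 6 of its members were lower and 1 higher (12 and 3 adjusted over the list alone; mean -0.17, adjusted p = 6.16e-04, but adjusted p = 0.163 with an estimated correlation). Of 19 bile acid genes, 2 were lower and 0 higher (6 and 0 adjusted over the list alone; adjusted p = 5.91e-06, and adjusted p = 0.0153 with an estimated correlation), namely Slc10a1 (-0.51) and the bile salt export pump Abcb11 (-0.44). Without C_MR_3438, 2 acute phase genes and 1 bile acid gene were still called lower (adjusted p = 1.46e-07 and 2.52e-05 for the lists).

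Of 34 genes of the urea cycle and amino acid catabolism, 6 were lower and 0 higher (19 and 0 adjusted over the list alone; adjusted p = 6.74e-13, but adjusted p = 0.0932 with an estimated correlation). Oat (-1.16), Prodh (-0.86), Asl (-0.63) and Gls2 (-0.79) led the list. Of 25 cholesterol genes, 0 passed (0 adjusted over the list alone) at a median of -0.46 (adjusted p = 5.91e-06, but adjusted p = 0.566 with an estimated correlation). Of 32 ATF4 targets, Asns and Vldlr (1.39) rose more with casein and 0 rose less (3 and 1 adjusted over the list alone; adjusted p = 0.0878, and adjusted p = 0.566 with an estimated correlation). Without C_MR_3438 the ATF4 list passed at the preset correlation (adjusted p = 0.0302), with 2 members higher and 0 lower. The NRF2 list had 1 higher and 0 lower of 35 (2 and 1 adjusted over the list alone; adjusted p = 0.1). Of 23 male-biased genes, Hsd3b5 differed (1 higher and 5 lower adjusted over the list alone; adjusted p = 0.00744, but adjusted p = 0.673 with an estimated correlation).

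**Figure D4:**
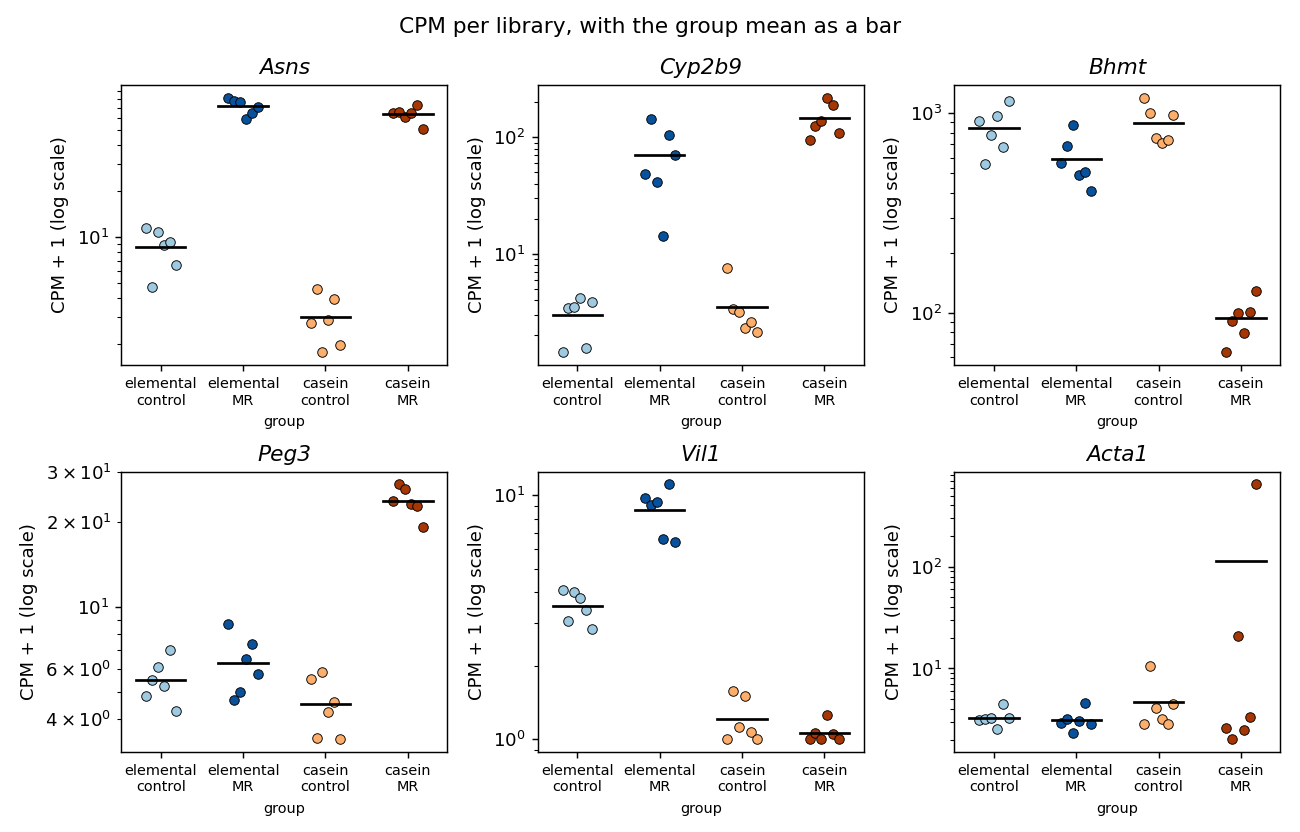
CPM of Asns, Cyp2b9, Bhmt, Peg3, Vil1 and Acta1 in each of the 24 libraries (y axes, CPM plus 1 on a log scale; x axes, group), with 1 point per library and a bar at the group mean. Peg3 is at 22.7 ± 2.80 CPM (SD, n = 6) in casein MR, and Acta1 is at 644 CPM in C_MR_3438.

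The control diets were compared with each other, casein minus elemental, to measure what the protein source did at 0.86% methionine. Vil1 was at 2.52 ± 0.52 CPM in elemental control and 0.209 ± 0.256 CPM in casein control (SD, n = 6; log2 fold change -3.58 ± 0.46, adjusted p = 2.78e-04). Asns was lower with casein (-1.96 ± 0.26, adjusted p = 2.78e-04), and so was Tcf24 (-2.58 ± 0.39, adjusted p = 0.00224). In all, 14 genes differed, 4 higher and 10 lower with casein, and 1578 genes had an unadjusted p under 0.05. The count was 74 with DESeq2, 3 with limma-voom and 7 in a fit of these 2 groups alone.

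Rcan2 (1.32 ± 0.23, adjusted p = 0.0168) and the mitochondrial epimerase Mcee (0.26 ± 0.05, adjusted p = 0.0467) were higher with casein control. The small RNAs Scarna17 (-1.05 ± 0.20) and Snord13 (-0.81 ± 0.16), the mitochondrial ribosomal RNAs mt-Rnr2 (-0.58 ± 0.10) and mt-Rnr1 (-0.55 ± 0.11) and the actin-binding gene Ablim1 (-0.54 ± 0.11) were lower. Under limma-voom the adjusted p was 0.122 for Tcf24 and Scarna17, 0.0969 for Rcan2 and Snord13, 0.0642 for Mcee and Ablim1 and 0.0543 for mt-Rnr1. Of the 24 fits that left out 1 library, the call was lost in 20 for Snord13, 19 for Mcee, 13 for Ablim1, 8 for Scarna17 and mt-Rnr1 and 2 for mt-Rnr2. Of 32 ATF4 targets, Asns alone was lower at an adjusted p under 0.05 (4 lower and 0 higher adjusted over the list alone; adjusted p = 0.00226, but adjusted p = 0.32 with an estimated correlation). Of 29 interferon-stimulated genes 0 passed (3 higher adjusted over the list alone), at a median of 0.30 (adjusted p = 6.53e-08, but adjusted p = 0.32 with an estimated correlation). For the difference between the MR effects this list had an adjusted p = 0.172, with 0 members called (0 adjusted over the list alone). Of 9 erythroid markers 0 passed (7 lower adjusted over the list alone; adjusted p = 2.99e-04, but adjusted p = 0.484 with an estimated correlation).

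The MR diets were compared with each other, casein minus elemental, at 0.17% methionine. The casein of the MR diet was oxidised, so protein source and oxidation cannot be told apart in this comparison. Vil1 was lower with casein, at 7.72 ± 1.83 CPM in elemental MR and 0.0605 ± 0.1 CPM in casein MR (SD, n = 6; log2 fold change -6.83 ± 0.48, adjusted p = 7.48e-10). Bhmt was lower by -2.65 ± 0.20 (adjusted p = 1.57e-09), and Igf1 stood at 993 ± 66.5 CPM in elemental MR and 728 ± 40.1 CPM in casein MR (-0.45 ± 0.08, adjusted p = 9.01e-04). In all, 873 genes differed, 365 higher and 508 lower with casein, and 174 of them at least 2-fold (111 higher, 63 lower). The 111 include the skeletal muscle genes named below, whose calls rested on C_MR_3438. The 2-fold counts were not taken without that library. With 1 surrogate variable 545 genes were called.

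The largest rises were those of skeletal muscle genes, Tnnc2 (5.84 ± 1.27), Acta1 (5.68 ± 1.23), Ttn, Myl1 (5.42 ± 1.23), Atp2a1 (5.37 ± 1.23), Tnni2 (5.26 ± 1.19), Tnnt3 (4.84 ± 1.10) and Ckm (4.80 ± 1.07). Without C_MR_3438 these 8 genes had values of 1.34, 1.26, 1.29, 1.23, 1.21, 1.06, 0.91 and 1.23 in the same order, and adjusted p between 0.204 for Ckm and 0.393 for Tnnt3. The largest falls after Vil1 were those of Ptgds (-4.01 ± 0.43), Hsd3b5 (-3.16 ± 0.67), Ncam2 (-3.12 ± 0.30) and Mmd2 (-2.74 ± 0.33), then Bhmt, Dct (-2.44 ± 0.67) and Slc22a7 (-2.38 ± 0.29). Under limma-voom the adjusted p was 0.0819 for Hsd3b5 and 0.485 for Dct. Without E_MR_3420 the value of Hsd3b5 was -1.94 (adjusted p = 0.0217), and the call of Dct was lost in 5 of the 24 fits that left out 1 library (highest adjusted p = 0.0708).

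Of 39 PPARalpha targets and genes of fatty acid oxidation, 24 were higher and 0 lower with casein MR than with elemental MR (28 and 0 adjusted over the list alone; adjusted p = 1.03e-24, and adjusted p = 0.0494 with an estimated correlation). Acot2 (1.5), the aldehyde dehydrogenase Aldh3a2 (0.96) and Pex11a (0.98) were among its leading members. Of 20 periportal markers, 14 were lower and 0 higher (15 and 0 adjusted over the list alone; adjusted p = 1.03e-24, and adjusted p = 4.67e-04 with an estimated correlation). Cyp2f2 (-1.21), Cdh1 (-0.77), Alb (-0.50) and Pigr (-0.88) led the list. Of 26 methionine cycle genes, 7 were lower and 0 higher (11 and 0 adjusted over the list alone; adjusted p = 7.04e-08, and adjusted p = 0.00149 with an estimated correlation), among them Pemt (-0.47). Of 34 urea cycle and amino acid catabolism genes, 17 were lower and 0 higher (24 and 1 adjusted over the list alone; adjusted p = 2.86e-15, but adjusted p = 0.0792 with an estimated correlation). Oat (-1.03), the urea cycle enzyme Ass1 (-0.89), Kynu (-0.62) and Sdsl (-0.76) led the list. Of 29 interferon-stimulated genes, 9 were higher and 0 lower (15 and 0 adjusted over the list alone; adjusted p = 9.21e-10, but adjusted p = 0.0888 with an estimated correlation). Zbp1 (0.99) led the list, which was also called on the control diets, though there too at the preset correlation alone (adjusted p = 0.32 with an estimated correlation). Of 20 Kupffer cell and macrophage markers 0 passed (0 adjusted over the list alone), at a median of 0.20 (adjusted p = 0.00404, but adjusted p = 0.621 with an estimated correlation). Without C_MR_3431 this median was 0.07 (adjusted p = 0.204). Of 10 genes of MHC class II antigen presentation 1 was higher (6 adjusted over the list alone), at a median of 0.59 (adjusted p = 2.5e-04, but adjusted p = 0.255 with an estimated correlation). Of 32 ATF4 targets, Vldlr (0.67) was higher and Shmt2 (-0.19) lower (the same adjusted over the list alone; adjusted p = 0.633).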

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

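The tests of muscle RNA and those of the casein MR pattern were chosen only after the result was seen. Of 752 sets of 6 libraries, 41 (5.45%) had 1 library far from the others, where chance marks about 1 in 20, or 37.6. The gap to the nearest other value, over the whole range, had to pass the limit of Dixon's test. They were among 24 sets of library measures (0), 128 of mean log2 CPM of lists (11) and 600 of genes (30). The sets of genes and lists overlap, so they are not independent.

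The first pattern was the skeletal muscle genes among the largest rises with casein MR. The 17 tested muscle markers, of 33 listed after the result was seen, summed to 2730 CPM in C_MR_3438, 123 in C_MR_3425 and 90.9 or less in the other 22 libraries. A rise of muscle genes across the casein MR livers was argued against, as 2 of the 6 casein MR libraries lay above every casein control library in mean log2 CPM of the markers. Skeletal muscle RNA in C_MR_3438 is a candidate explanation, since without it the median log2 fold change of the markers went from 4.45 to 0.41 and the number called higher from 16 to 2. Those 2 were Cox6a2 (2.05, adjusted p = 2.13e-04) and Tpm2 (1.30, adjusted p = 6.99e-05), and Neb (-1.60, adjusted p = 1.18e-05) fell, while how muscle RNA entered the sample was not tested.

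The second pattern was the 14 genes that differed between the control diets. A single library was argued against for Asns, Tcf24 and Vil1, as in 0 of 24 fits that left out 1 library was any of them no longer called (highest adjusted p = 0.0123). MR libraries are not part of the 2 group means compared, but they share the estimate of the spread. The count of genes called was 7 without E_MR_3424 and 9 without C_MR_3412. The fits without a control library tested such dependence most directly. For the noncoding RNAs, more RNA without poly(A) tails in the elemental control libraries stays open as a technical explanation. A set of 66 other genes, of small nuclear, nucleolar and Cajal body RNAs, ribosomal RNA and histones, had a median log2 fold change of -0.37 (exact permutation p = 0.039 for their mean per library, adjusted p = 0.039). The histone genes, H1f0 among them, were taken by symbol and were not checked for poly(A) tails. For Asns, an integrated stress response already higher on the elemental control diet stays open as a biological explanation. The other 19 ATF4 targets that rose with elemental MR had a mean log2 CPM of 2.41 ± 0.165 in elemental control and 2.14 ± 0.184 in casein control (SD, n = 6; exact permutation p = 0.0303, adjusted p = 0.039).

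The third pattern was the lower periportal, urea cycle and acute phase genes with casein MR beyond the elemental MR effect. The periportal and urea cycle lists share members, Ass1 and Gls2 among them, so they are not independent. For the periportal genes a smaller share of hepatocytes was argued against as the whole cause. Their difference in mean log2 CPM was below that of pericentral markers (-0.39, 95% interval -0.64 to -0.14). The periportal list was taken up after its call was seen, and this interval makes no allowance for that choice. A wrong scale moves all genes of a library alike, so it cannot move the differences of the lists minus all other tested genes. These were -0.692 (-0.924 to -0.459) for periportal, -0.361 (-0.573 to -0.148) for urea cycle and -0.451 (-0.692 to -0.209) for acute phase genes. The lists were taken up because camera, which also compares a list with the other genes, had called them. These values therefore repeat that result and are no independent test. The library with muscle RNA was argued against as the whole cause by 9 periportal members still called lower without it, and by differences without it of -0.353 (-0.565 to -0.14) for urea cycle and -0.419 (-0.673 to -0.164) for acute phase genes, although called acute phase members went from 4 to 2. A smaller share of hepatocytes stays open for urea cycle (-0.0797 against pericentral markers, -0.279 to 0.119) and acute phase genes (-0.149, -0.461 to 0.162), as pericentral markers were lower too (-0.281, and -0.244 without C_MR_3431), the Kupffer cell list had a value of 0.192 (-0.21 to 0.595, and 0.0857 without C_MR_3431) and the endothelial list of 0.0111 (-0.0707 to 0.093). Also open are, for acute phase genes, a level already higher in casein control (mean difference of 0.285 between the control diets, against -0.166 between the MR diets), which was not tested further, a fasting-like state, as the median difference of Pck1, Igfbp1, Ppargc1a and Pdk4 was -0.0455 but the 95% interval of Pdk4 ran from -0.92 to 2.09, and an effect of the oxidised casein diet, which was not tested apart from the protein source.

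The gene counts were compared with 50 splits of the same libraries, the real one included. None of the 49 exchanged splits reached the real count of genes called with elemental MR (1803, highest other 4) or casein MR (3137, highest other 632). The same held for the difference (315, highest other 1), the control diets (14, highest other 11) and the MR diets (873, highest other 67). In each of these, 1 split of the 50, the real one, reached the value, and 50 splits cannot show a smaller share. Exchanged groups mix libraries of different diets, which can widen their spread and lower their counts. The margin for the control diets was small, and that count ran from 5 to 33 with 1 library left out. The splits do not decide on the 1260 shared genes (highest other 0), as 0 of the 49 others called genes in both comparisons. For the lists called at the preset correlation with casein MR, 2 splits reached 21 (highest other 21). The exchanged split that matched the real one also called 632 genes and may have kept part of the difference between the diets. The splits thus cannot decide on these lists, and chance is not excluded. Nor could chance be excluded for the lists called with elemental MR (17, highest other 20, 3 splits) and the difference (15, highest other 19, 7 splits). The same holds for the control diets (10, highest other 15, 17 splits) and the MR diets (15, highest other 19, 5 splits).

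Lists had 1 library far from the others in mean log2 CPM as follows. The glucose metabolism list was at 5.89 in C_MR_3412 (others 6.18 to 6.25), and the hepatokine list was at 5.78 in C_MR_3419 (others 5.32 to 5.47). The cell cycle list was at 1.43 in C_C_3407 (others 0.49 to 0.77), and the p53 list was at 2.79 in E_C_3418 (others 2.32 to 2.46). The p53 list was at 2.73 in C_C_3407 (others 2.35 to 2.45), and the pericentral list was at 5.68 in C_MR_3431 (others 5.86 to 5.94). The periportal list was at 7.68 in C_MR_3412 (others 7.96 to 8.08), and the Kupffer cell list was at 5.10 in C_MR_3431 (others 4.41 to 4.50). The cholangiocyte list was at 1.96 in E_C_3427 (others 1.44 to 1.60), and the adipose list was at 3.49 in C_MR_3438 (others 2.46 to 2.81). The pancreas list (Cela1 alone) was at 8.54 in E_C_3430 (others 4.41 to 5.83).

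In elemental control, these genes had 1 library far from the others (CPM). Gsta4 was at 28.3 in E_C_3401 (others 41.6 to 49.7). Usp18 was at 4.88 in E_C_3428 (others 7.27 to 8.54). Dhcr7 was at 42.1 in E_C_3417 (others 59.3 to 70.4). Pigr was at 380 in E_C_3428 (others 489 to 561). Cux2 was at 0.308 in E_C_3401 (others 0.642 to 0.812).

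In elemental MR there were these. Serpina4-ps1 was at 2.09 in E_MR_3420 (others 0 to 0.0623). Creld2 was at 20.3 in E_MR_3403 (others 12 to 14.1). Shmt1 was at 144 in E_MR_3403 (others 115 to 124). Igtp was at 66.8 in E_MR_3420 (others 42.1 to 48.2). Snord13 was at 201 in E_MR_3416 (others 341 to 412). Lepr was at 3.16 in E_MR_3420 (others 5.48 to 6.86).

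In casein control there were these. Psat1 was at 0 in C_C_3437 (others 0.704 to 1.62). Gars was at 37.2 in C_C_3421 (others 39.5 to 40.4). Ephx1 was at 109 in C_C_3413 (others 155 to 191). Acta1 was at 9.63 in C_C_3413 (others 1.87 to 3.45). Zbp1 was at 3.93 in C_C_3421 (others 5.93 to 7.24). Ifi44 was at 21.5 in C_C_3407 (others 11.5 to 14). Ghr was at 400 in C_C_3407 (others 461 to 498).

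In casein MR there were these. Cox6a2 was at 112 in C_MR_3438 (others 1.36 to 6.9) and Bhlhe41 was at 0 in C_MR_3431 (others 0.566 to 1.55). Ddit4 was at 16.3 in C_MR_3433 (others 5.01 to 7.62) and Fasn was at 216 in C_MR_3412 (others 121 to 147). Cpt1a was at 226 in C_MR_3433 (others 164 to 183) and Igf1 was at 651 in C_MR_3438 (others 726 to 766). Pck1 was at 526 in C_MR_3412 (others 1220 to 1880) and Shmt1 was at 132 in C_MR_3425 (others 104 to 112). Vil1 was at 0.258 in C_MR_3431 (others 0 to 0.0574) and Pex11a was at 801 in C_MR_3412 (others 419 to 529). Lepr was at 4.74 in C_MR_3412 (others 11.9 to 18.1) and Khk was at 155 in C_MR_3412 (others 193 to 217). C_MR_3412 had 5 of these genes, the most of any library.

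The effects of MR with casein and with elemental amino acids differed, by the test of the difference in edgeR, for these named genes, with differences of log2 fold changes (casein minus elemental). Cspg5 3.49, Slc35f2 3.15, Mogat1 2.53, Krt23 2.53, Peg3 2.41, Sema5b 2.41 and Ehhadh 2.40 had positive differences. Cyp4a31 2.35, Adgrg2 2.33, Cyp4a14 2.17, Lpl 2.08, Tcf24 2.02, Asns 1.78 and Acot1 1.73 had positive differences. Acot2 1.68, Vldlr 1.39, Scarna17 1.26, Hspb1 1.19, Snord13 0.94 and Aldh3a2 0.85 had positive differences. Gstm4 0.66, mt-Rnr2 0.54 and Acadl 0.38 had positive differences. Hsd3b5 -3.42, Ptgds -3.27, Vil1 -3.25, Dct -2.88, Ncam2 -2.80, Bhmt -2.74 and Nnmt -2.58 had negative differences. Apoa4 -2.51, Slc22a7 -2.16, Mmd2 -1.95, Serpina12 -1.76, Orm1 -1.62, Aldh1b1 -1.47 and Pigr -1.32 had negative differences. Cyp2f2 -1.22, Oat -1.16, Prodh -0.86, Gulo -0.84, Ass1 -0.79 and Gls2 -0.79 had negative differences. Lect2 -0.79, Gnmt -0.75, Ahsg -0.72, Cdh1 -0.65, Asl -0.63, Gamt -0.56 and Slc10a1 -0.51 had negative differences. Igf1 -0.50, Abcb11 -0.44, Otc -0.42, Ghr -0.41, Mcee -0.37, Fga -0.36 and Alb -0.36 had negative differences. Scarna17, Snord13, mt-Rnr2 and Mcee were named because they differed between the control diets, at -1.05, -0.81, -0.58 and 0.26. The difference between the MR effects uses the same control libraries, so for these genes it is no independent result and may lie in the controls. The lists called at the preset correlation had these median differences: methionine cycle and sulfur amino acid metabolism -0.22, cholesterol synthesis and uptake -0.46, PPARalpha targets and fatty acid oxidation 0.39, bile acid synthesis and transport -0.27, glucose metabolism and insulin signalling -0.16, urea cycle and amino acid catabolism -0.32, secreted hepatokines and growth hormone axis -0.11, male-biased liver genes -0.54, CAR and PXR xenobiotic targets -0.19, acute phase response -0.35, cell cycle and proliferation 0.29, immediate early and heat shock genes 0.25, pericentral hepatocytes -0.18, periportal hepatocytes -0.54 and Kupffer cells and macrophages 0.20. The call of the heat shock list was lost without C_MR_3438 (adjusted p = 0.0522) and that of the Kupffer cell list without C_MR_3431 (adjusted p = 0.302). Of these lists, 5 were also called with an estimated correlation, namely periportal hepatocytes, PPARalpha targets, the methionine cycle, bile acids and acute phase.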

How the results depend on the processing

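The robust prior, and the count of list members without C_MR_3438, were tests chosen only after the result was seen. The 6 gene counts stayed within 1.5 times their value, with the exceptions given here, under DESeq2 size factors, upper quartile scaling, no filter, a stricter filter, 1 surrogate variable, a robust prior, the DESeq2 Wald test, limma-voom and a fit of the compared groups alone, where these apply. With 1 surrogate variable the count was 2052 for casein MR, 193 for the difference and 545 for the MR diets, and 6 lists were called on the control diets. The control diets gave 74 genes with the DESeq2 Wald test, 3 with limma-voom and 7 in a fit of only the 2 groups compared. The cause was not tested in any of these. Upper quartile scaling gave 12 genes on the control diets, 2 higher and 10 lower, and with elemental MR it gave 807 higher and 945 lower.

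A stricter threshold gave fewer genes by construction. At an adjusted p under 0.01 there were 974 with elemental MR, 153 for the difference, 3 on the control diets, 450 on the MR diets and 718 shared. With at least a 2-fold change there were 327 with elemental MR, 674 with casein MR, 97 for the difference, 6 on the control diets, 174 on the MR diets and 244 shared. With an estimated correlation camera called 4 lists with elemental MR, 9 with casein MR, 5 for the difference, 0 on the control diets and 3 on the MR diets.

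Leaving out 1 library gave 1400 (without E_MR_3405) to 1903 genes (without C_C_3407) with elemental MR, 2851 (C_C_3413) to 3174 (E_C_3428) with casein MR, 227 (C_C_3413) to 404 (C_C_3407) for the difference, 664 (E_MR_3403) to 952 (C_C_3407) on the MR diets and 1061 (E_MR_3405) to 1277 (E_C_3428) shared. On the control diets it gave 5 to 33 genes, namely 33 without C_C_3407, 9 without E_C_3417 or C_MR_3412, 7 without E_C_3418, E_MR_3424 or C_C_3413 or C_C_3429, and 5 without E_C_3428 or C_C_3421 or C_C_3436. Lists called ran from 16 to 19, 20 to 23, 13 to 18, 5 (without C_C_3437) to 13 (without C_C_3407) and 13 to 17 in the order elemental MR, casein MR, difference, control diets and MR diets.

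Among named genes, 6312 results under other settings stayed on their side of the threshold, 125 fell short of it and 57 passed it newly, and 0 reversed. Leaving out 1 library gave 17588, 321 and 91 in the same order. For lists the counts were 1034, 71 and 15 under other settings and 3693, 66 and 81 with 1 library left out. Over the alternatives that keep every library, the adjusted p ran from 8.92e-06 to 0.143 for Cox6a2 with elemental MR, and for the difference from 0.0122 to 0.156 for Hsd3b5, 2.82e-04 to 0.125 for Vil1 and 0.004 to 0.523 for Dct. On the control diets the highest was 0.0228 for Vil1, 0.0396 for Asns, 0.122 for Tcf24 and Scarna17, 0.0969 for Rcan2 and Snord13, 0.156 for Mcee, 0.138 for Ablim1, 0.0733 for mt-Rnr1 and 0.0475 for mt-Rnr2. On the MR diets it was 0.0819 for Hsd3b5 and 0.485 for Dct. No paired analysis was possible because the groups share no replicate numbers. At these depths, genes near 0.0605 CPM, such as Vil1 in casein MR, rest on few reads per library.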

Other observations

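Other lists moved with MR and are given here as values. The tests of Bcl6, Cux2 and the gene copies were written down before their results were seen, and the tests of Lpl and of genes with opposite effects were chosen only after the result was seen. Of 30 hepatokines and genes of the growth hormone axis, 4 rose and 4 fell with elemental MR (7 and 5 adjusted over the list alone; adjusted p = 0.892), and 3 rose and 9 fell with casein MR (7 and 10 adjusted over the list alone; adjusted p = 0.0474, but adjusted p = 0.073 without C_MR_3438 and adjusted p = 0.218 with an estimated correlation). The growth hormone receptor gene Ghr fell by 0.75 (log2, SE 0.08) with elemental MR and by 1.16 (SE 0.08) with casein MR, and the leptin receptor gene Lepr rose by 2.50 ± 0.39 with casein MR and had a value of 0.83 ± 0.38 (adjusted p = 0.162) with elemental MR. Of 24 CAR and PXR targets, 11 rose and 3 fell with elemental MR (15 and 3 adjusted over the list alone; adjusted p = 5.03e-06, but adjusted p = 0.0772 with an estimated correlation), and 8 rose and 6 fell with casein MR (the same adjusted over the list alone; adjusted p = 0.0714), with Cyp2c38 at 1.68 ± 0.24 and 1.93 ± 0.24. Among these 24 targets, 6 are also in other lists, such as Cyp2b9 in the female-biased list, so the lists are not independent. Of 22 genes of glucose metabolism, 1 rose and 3 fell with elemental MR (2 and 4 adjusted over the list alone; adjusted p = 0.714), and 0 rose and 9 fell with casein MR (1 and 9 adjusted over the list alone; adjusted p = 0.0179, but adjusted p = 0.401 with an estimated correlation). Glycogen phosphorylase (Pygl) fell by 0.47 (SE 0.08) and 0.78 (SE 0.08) and ketohexokinase (Khk) by 0.50 (SE 0.10) and 0.83 (SE 0.10).

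Of 16 p53 targets, 2 rose and 1 fell with elemental MR (3 and 2 adjusted over the list alone; adjusted p = 0.976) and 3 rose and 1 fell with casein MR (the same adjusted over the list alone; adjusted p = 0.379), among them Gadd45b (2.79 ± 0.41 and 3.29 ± 0.42) and Sesn2 (0.56 ± 0.16 and 0.64 ± 0.16). Of 9 erythroid markers, 1 rose and 3 fell with elemental MR (the same adjusted over the list alone; adjusted p = 0.00896, but adjusted p = 0.416 with an estimated correlation), and 1 rose and 2 fell with casein MR (the same adjusted over the list alone; adjusted p = 0.281). Car1 fell by 1.86 (SE 0.33) with elemental MR and by 1.91 (SE 0.31) with casein MR, Alas2, of haem synthesis, by 0.90 (SE 0.20) and 1.40 (SE 0.20), and the transferrin receptor gene Tfrc rose by 0.92 ± 0.20 and 1.08 ± 0.20. Of 24 cell cycle genes, 3 fell with elemental MR (3 adjusted over the list alone; adjusted p = 0.0628) and 1 fell with casein MR (1 adjusted over the list alone; adjusted p = 0.798), and of 10 genes of MHC class II antigen presentation 0 passed in either (0 adjusted over the list alone; adjusted p = 0.83 and 0.37).

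Some genes were singled out after their values were seen. Lipoprotein lipase (Lpl) stood at 40.5 ± 8.44, 42.3 ± 15, 36.7 ± 4.26 and 162 ± 60.2 CPM in elemental control, elemental MR, casein control and casein MR (SD, n = 6), with a difference between the MR effects of 2.08 ± 0.30 (SE, edgeR adjusted p = 1.51e-04). Of the 11 genes called in opposite directions, Ahsg, a secreted hepatokine, was at 0.33 ± 0.10 with elemental MR and -0.39 ± 0.10 with casein MR, and Cspg5 was at -1.96 ± 0.46 and 1.52 ± 0.43. Others were Cmtm8, Slc35f2, Sema5b, Med12l, Cyp2a12, 4930581F22Rik and Bhlhb9.

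The lower male-biased and higher female-biased genes with MR were set against explanations. For the male-biased genes, reads shared between near-identical copies were argued against as the whole cause. The 11 of them outside the families set apart had a median log2 fold change of -1.29 with elemental MR and -1.67 with casein MR. Those families were Cyp2a, Cyp2b, Cyp3a, Cyp4a, Mup, Serpina1, Ugt2b, Slc22a2, Sult and Hsd3b, and the 11 genes were not checked for copies of their own. The rise of the female-biased genes was not tested in this way. A female pattern of growth hormone signalling in MR livers may be a biological explanation, and 2 of 4 tests of Bcl6 falling or Cux2 rising passed. Bcl6, a male-biased repressor, fell by 2.22 (SE 0.64, adjusted p = 0.0111) with casein MR and had a value of 0.11 ± 0.61 (adjusted p = 0.942) with elemental MR. Cux2, a female-specific repressor, rose by 2.61 ± 0.57 (adjusted p = 0.0011) with casein MR and had a value of 1.59 ± 0.56 (adjusted p = 0.0572) with elemental MR, so these tests leave the explanation open.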
